A study of Mus musculus with 20 samples.

How the data were processed

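Bulk RNA sequencing was analysed for 20 tumours of B16F10, a mouse melanoma line of C57BL/6 origin, grown in mice of that strain. The labels assign 5 tumours each to control IgG, propafenone, anti-PD-1 and the combination of propafenone with anti-PD-1. Each tumour was taken as 1 independent library, as far as the labels say, since they do not state whether any pair came from 1 animal. Replicate numbers were checked for pairing across groups and did not pair the libraries: the 30 same-number pairs had a mean correlation of -0.00694 (range -0.41 to 0.369) after group means were removed, and 7 of 20 libraries correlated best with a library of their own number.

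The deposited gene table holds expected counts, estimated read counts per gene stored as whole numbers and not scaled to a common total. Among low values 4 and 8 are more frequent than their neighbours, and how many counts stand for 1 sequenced fragment is not known. A second deposited table holds TPM, a transcript abundance per length made by the authors, with each column summing to a common total; it served as an alternative only. The submitters' processing notes name FastQC, HISAT2 2.2.1, SAMtools 1.9 and the builds GRCm38 and mm10. The tool that counted reads per gene, the annotation release and the strand setting were not given in the sources used here. Library preparation used a SMARTER mRNA kit per the labels.

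The expected counts summed to between 56 and 64.5 M (M, 1e6) per library. At 4 counts per fragment, an assumption made from the low values, this would be near 14 to 16.1 M fragments. Group means ± SD (n = 5) were 60.4 ± 1.14 M for IgG, 62.4 ± 0.628 M for propafenone, 60.6 ± 2.75 M for anti-PD-1 and 62.4 ± 1.31 M for the combination. All 20 columns were used. The table lists 32285 genes, of which 32158 identifiers were found in GENCODE mouse release 21, the source of the GRCm38 coordinates. No library was a copy of another of its group. Over the 40 within-group pairs the lowest chi-square per degree of freedom was 4.43, computed on counts divided by 4 under that assumption. Within-group correlations of log2 CPM, counts scaled to a common library total, ran from 0.958 to 0.986. Pairs across groups were not checked in this way.

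Genes were tested in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr on the 4 groups, robust quasi-likelihood fit, 1 mean per group over all 20 libraries, 16 residual degrees of freedom). The filter kept 15875 genes holding 99.98% of the counts. The common biological coefficient of variation was 0.252 and the median prior degrees of freedom 4.52. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. The 6 contrasts were the 5 pairwise comparisons and the interaction, which is the combination effect minus the sum of the single effects on the log2 scale. Standard errors of log2 fold changes are the size of the fold change divided by the square root of the F statistic. CPM values use TMM-scaled library sizes.

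Gene lists were tested with camera of limma 3.58.1 on voom values, with the preset correlation between genes of 0.01, adjusted over the 40 of 41 lists with at least 5 measured members. The NK cell list had 4 measured members of 11 and was not tested. Beside each call stands the adjusted p with a correlation estimated from the data, and fry, which tests whether a list's genes move one way on balance or, in its mixed form, in either direction, was run as another tool. A list score per library is the mean over members of log2 CPM centred on all libraries. The counts adjusted over the list alone apply the adjustment to the members of 1 list. These lists, the tests, the contrasts, the choice of genes to name and the alternatives of scaling, filter, test, pseudocount (0.1 and 1), fold minimum (1.5) and single left-out libraries were set before the data were examined. Chosen after the values were seen were counts divided by 4, covariates of muscle, red blood cell and macrophage list scores, leaving out the 5 libraries above 1000 CPM of Hbb-bs, and the exact permutation of list means over tumours. With 5 tumours in each group this permutation has 252 assignments, and its p cannot fall under 0.0079. Adjusted over 40 lists, a few lists at that smallest p cannot be called, and adjusted p-values come in steps. A count of 0 by this test therefore does not show that no list shifted.

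Genes are named by a fixed rule. In each comparison they are up to 8 genes with the smallest p in each direction that passed, kept their direction in each fit without 1 library, averaged at least 1 CPM and carry an ordinary symbol. Where fewer than 3 passed, the 3 smallest p are given as values that did not pass. A fixed panel of 14 genes follows: Hmox1, Gpx4, Slc7a11, Acsl4, Tfrc, Fth1, Jun, Cd8a, Gzmb, Prf1, Ifng, Pdcd1, Cd274 and Mitf. For each called list up to 3 members with the smallest p in its direction are named, and members past the threshold against it may be. Other genes named were chosen after their values were seen. Some members that this rule picks are not reported here.

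The gene test was tested on simulated data, negative binomial counts drawn gene by gene with the means and spreads of these libraries, in which 50 genes per fold were given a known change. For the combination against IgG it recovered 16% of genes at a fold of 1.3, 46% at 1.5, 64% at 2 and 84% at 4, with 3 false calls. For the interaction it recovered 12% at 1.5, 48% at 2 and 78% at 4, with 5 false calls. Genes were drawn independently of each other, so variation that many genes share within a tumour is absent. Recovery and false calls in the deposited counts may therefore differ. In a simulated list shift, with genes drawn independently of each other, camera called the shifted cholesterol synthesis list and 0 others. DESeq2 1.42.0, limma voom and limma on log2 TPM were run as other tools. Other splits of the same libraries were refitted, 30 per comparison for gene counts and 100 for list counts. The edgeR p-values measure the spread between tumours of this series. Camera p-values at the preset correlation set a list's genes against the other genes and take genes as nearly independent.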

Results

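Tumours of the melanoma line B16F10 were compared after control IgG, propafenone, anti-PD-1, or propafenone with anti-PD-1, with 5 tumours per group. Propafenone is an antiarrhythmic drug that blocks cardiac sodium channels, and anti-PD-1 is an antibody against an inhibitory receptor of T cells. The title of the series names ferroptosis, a cell death by iron-dependent lipid peroxidation, and synergy with immunotherapy as its subject. Treatment began at a tumour volume near 100 mm3 and tumours were taken on day 16. Against IgG tumours, combination tumours had macrophage, chemokine and fibroblast lists called higher, muscle markers higher beside them (mean log2 change 4.41), and the hypoxia and glycolysis list called lower. With a correlation estimated from the data camera called none of these lists (adjusted p = 0.16, 0.16, 0.23, 0.33 and 0.22). On the first principal component of log2 CPM, which held 25.5% of the variance, the 5 combination tumours lay between 34.2 and 55.0 and the 5 IgG tumours between -60.7 and -5.11. Component 2 held 13.3%. All 6 contrasts were tested on 15875 genes. Camera with its preset correlation called a median of 12 to 16 of 40 lists when the same tumours were split into other groups. The edgeR p-values measure the spread between tumours. Camera p-values at the preset correlation set a list's genes against the other genes and take genes as nearly independent.

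**Figure D1:**
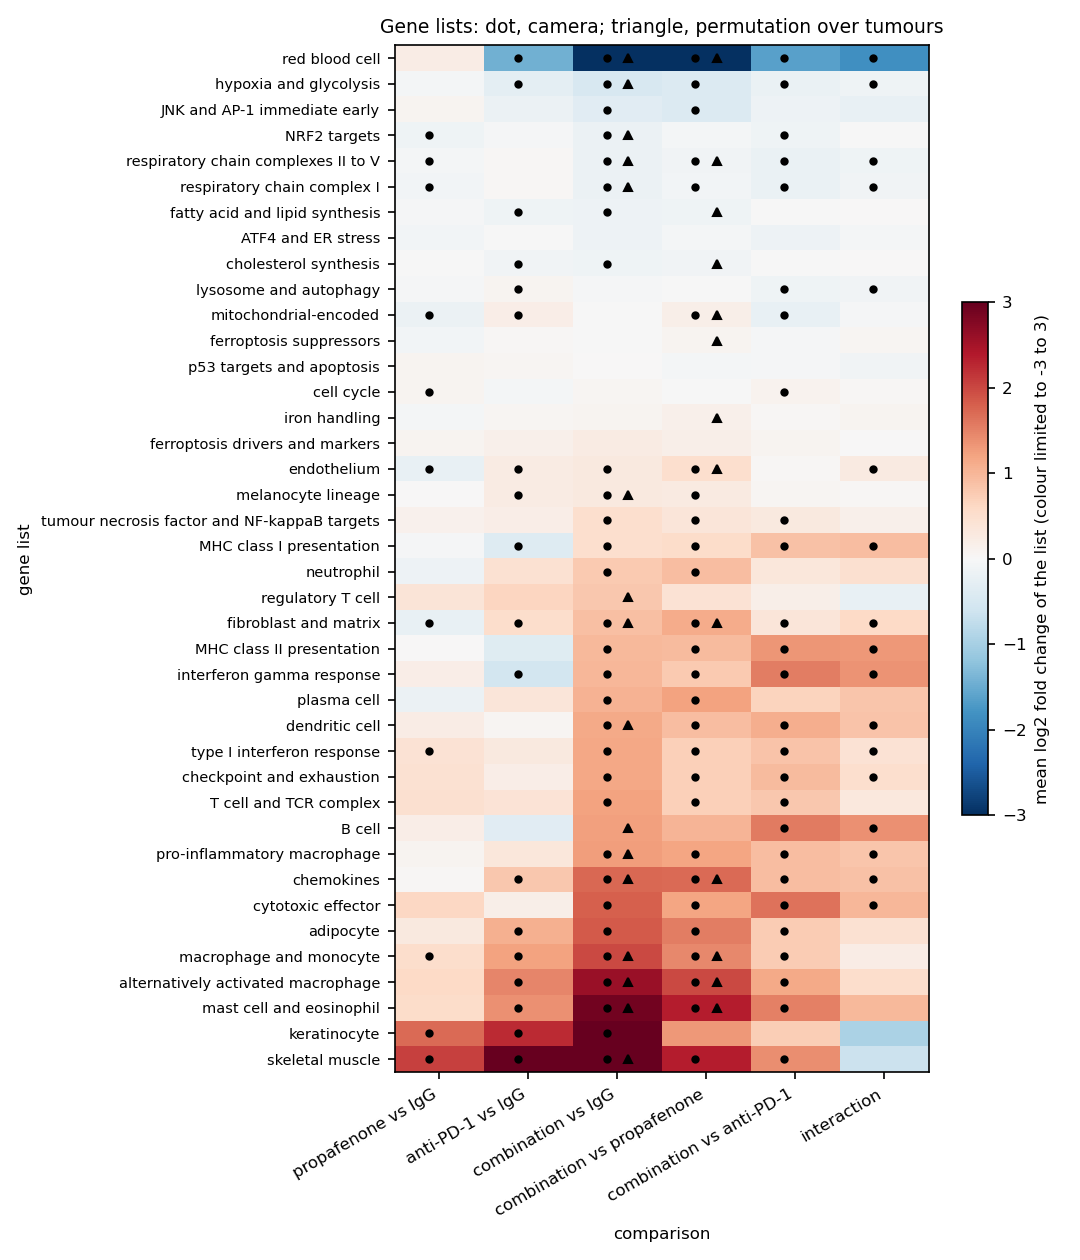
Mean log2 fold change of each tested gene list (vertical axis) in each comparison (horizontal axis), with the colour limited to -3 and 3, a dot where camera called the list and a triangle where an exact permutation over tumours did. Camera called 30 of 40 lists between combination and IgG tumours and the permutation 16, and with a correlation estimated from the data camera called 0 in each column. The keratinocyte values include genes listed at 0 in all IgG tumours and are not bounds.

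Propafenone alone left the panel genes tied to ferroptosis without a call. Hmox1, the haem-degrading enzyme often raised in ferroptotic cells, measured 122 ± 36.8 CPM after propafenone and 140 ± 32.7 CPM after IgG (mean ± SD, n = 5 each, log2 fold change -0.20 ± 0.303 SE, edgeR adjusted p = 0.95). Gpx4, the peroxidase that removes lipid peroxides, measured 235 ± 30.5 and 263 ± 18.9 CPM (-0.16). Slc7a11, the cystine transporter, stood at -0.59, Acsl4, which loads polyunsaturated fatty acids into lipids, at 0.28, Tfrc, the transferrin receptor, at 0.12 and Fth1, the ferritin heavy chain, at -0.18, with adjusted p of 0.91 to 0.92. The smallest p among genes higher after propafenone belonged to Arhgef37 (0.55), Deptor (0.57), an inhibitor of mTOR, and Intu (0.40). Among genes lower they belonged to the stress-induced factor Atf5 (-0.58), Serpine2 (-0.88), a protease inhibitor, and Crip2 (-0.29), and all 6 had adjusted p = 0.91. edgeR called 0 of 15875 genes, with 754 at an unadjusted p under 0.05 where 794 would fall by chance. limma voom and limma on log2(TPM + 1) and on log2(TPM + 0.1) called 0, and DESeq2 called 3, Pcdhga10, Krt1 and Krt77, named after their values were seen, each listed at 0 in all 5 tumours of 1 of the groups. In simulated data with genes drawn independently, the edgeR test recovered 46% of genes changed 1.5-fold and 66% of genes changed 2-fold.

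Camera called 11 lists after propafenone. The mitochondrial groups were lower by little: respiratory chain complex I, the NADH dehydrogenase, had 36 of 37 members lower and a mean log2 change of -0.094 (camera adjusted p = 6.58e-05, adjusted p = 0.98 with an estimated correlation), complexes II to V -0.068 (0.000789, 0.98) and the 13 genes of mitochondrial DNA -0.19 (0.000116, 0.98). Members with the smallest p were Ndufs6 (-0.24), Ndufs5 (-0.18), Atp5g2 (-0.24), Atp5e (-0.22), mt-Nd3 (-0.25) and mt-Nd4 (-0.27), none past the threshold. No random lists of like transcript length and expression were drawn for this comparison, so a fall particular to these lists was not tested. NRF2 targets, the antioxidant genes, had a mean of -0.13 (0.00116, 0.29), led by Tkt (-0.18), Gstm1 (-0.24) and Nqo1 (-0.33). Endothelium (-0.23, 0.000789, 0.98), with Eng, Plvap and Robo4 at -0.21, -0.39 and -0.50, and fibroblast genes (-0.22, 0.02, 0.98), with Col6a1 at -0.52 and Bgn at -0.43, were also called lower. Type I interferon response (0.43, 0.0024, 0.98), with Ifit3 and Xaf1 at 0.81 and 0.77, macrophage genes (0.53, 0.00503, 0.98), with Fcgr1 at 0.65, and cell cycle (0.079, 0.0123, 0.98), with Kif20a at 0.24, were called higher. Markers of neighbouring tissue moved with them, as skeletal muscle (2.05, 0.0053, 0.98), with Myh4 at 3.11, and keratinocyte genes (0.0304, 0.98) such as Krt10 were also called higher. Ferroptosis suppressors (-0.086, 0.198), ferroptosis drivers (mean 0.072, median -0.055, 0.756) and iron handling (-0.068, 0.744) were not called by camera. Without IgG replicate 3 camera called 7 lists, without the 5 libraries high in the haemoglobin gene Hbb-bs it called 3, of which 1 was among the 11, fry and the exact permutation over tumours called 0 on all libraries, and 0 members of any list passed when adjusted over the list alone. Of the 11 lists 4 were called in each of 20 fits without 1 library. The macrophage call ended without IgG 1 (0.29), IgG 3 (0.31) and propafenone 4 (0.325), and the mean was 0.83 and 0.86 without IgG 2 and IgG 4. The type I interferon call ended without IgG 1, IgG 3 and propafenone 4 (0.25), with 0.66 and 0.79 without IgG 2 and propafenone 1. The fibroblast call ended without IgG 4 (-0.066), IgG 5 (-0.12), propafenone 1 (-0.13) and propafenone 3 (-0.13), and endothelium without propafenone 3 (-0.105), with -0.15 without propafenone 5. Cell cycle ended without IgG 1, IgG 3, propafenone 1 and propafenone 2 (0.049), with 0.12 without IgG 4, complexes II to V without propafenone 4, and keratinocyte in 11 fits. Without IgG 5 complex I stood at -0.057, complexes II to V at -0.04 and mitochondrial-encoded genes at -0.11.

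Anti-PD-1 alone gave no gene past the threshold either. Postn, which encodes the matrix protein periostin, stood at 0.93 ± 0.179 (log2 ± SE, edgeR adjusted p = 0.35), Pvalb, the calcium buffer of fast muscle, at 3.49 and Ltbp4, a TGF-beta binding protein, at 0.81. Lower were Dpf1 (-1.09), Tut1 (-0.31) and Sapcd2 (-0.40), all at 0.38. In the panel Cd8a, the CD8 chain of cytotoxic T cells, measured 0.529 CPM after anti-PD-1 and 0.591 CPM after IgG, Ifng stood at -1.86 with adjusted p = 0.77, and Gzmb, Prf1, Pdcd1, Cd274 and Mitf stood between -0.03 and 0.42. edgeR called 0 genes, with 1203 at an unadjusted p under 0.05, limma voom and both TPM fits 0, and DESeq2 21. Without IgG replicate 4 edgeR called 1 gene, the growth factor Igf1 (2.15, adjusted p = 0.033), and without anti-PD-1 replicate 2 it called 1, Pvalb (3.81, 0.0063), both named here because the counts were 1. Without the 5 libraries high in Hbb-bs edgeR called 13, of which 10 were higher and 3 lower. In simulated data with genes drawn independently, the test recovered 52% of genes changed 1.5-fold and 78% of genes changed 2-fold.

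The macrophage and monocyte list was higher after anti-PD-1 in all 20 members, with a mean log2 change of 1.21 (camera adjusted p = 1.42e-14, adjusted p = 0.47 with an estimated correlation) and Cd14 at 1.12, Mertk at 0.56 and Mrc1, the mannose receptor, at 1.04. Alternatively activated macrophage genes (1.46, 3.61e-06, 0.47), with Mgl2 at 1.34, chemokines (0.81, 5.98e-05, 0.48), with Ccl12, Cxcl14 and Ccl9 at 1.01, 1.56 and 1.02, and mast cell genes (1.38, 0.0127, 0.48), with Tpsb2 at 1.88, were called higher. So were fibroblast genes (0.53, 1.02e-07, 0.48), with Fap at 1.05 and Pdgfra at 0.64, and endothelium (0.25, 0.000874, 0.48), with Tek at 1.03. Melanocyte lineage (0.23, 1.04e-06, 0.47) stood higher with the pigment genes Oca2 (0.47), Slc24a5 (0.39) and Slc45a2 (0.27), and so did mitochondrial-encoded genes (0.19, 2.47e-05, 0.48), with mt-Nd5 at 0.28, and lysosome genes (0.088, 0.00253, 0.48), with Ctsd at 0.29. Hypoxia and glycolysis was lower in 22 of 23 members (-0.28, 3.03e-08, 0.48), with the lactate exporter Slc16a3 at -0.45 and Bnip3 at -0.42. That list was not set against random lists of like transcript length and expression. Interferon gamma response (-0.55, 0.015, 0.71) and MHC class I presentation (-0.38, 0.0266, 0.71) were called lower, both with Nlrc5 at -0.69, as were cholesterol synthesis (-0.10, 0.00521, 0.48), with Fdft1 at -0.17, and fatty acid synthesis (-0.14, 0.0117, 0.48), with Me1 at -0.28. Markers of other tissues moved with these lists: skeletal muscle (3.01, 2.71e-06, 0.48; 13 members adjusted over the list alone), keratinocyte (0.000797, 0.56; 8 members, Krt5 and Krt14 among the smallest p) and adipocyte genes (1.07, 0.0185, 0.56), with Plin4 at 1.96, were higher and red blood cell genes (-1.43, 0.0117, 0.56), with Slc4a1 at -2.35, lower. Ferroptosis suppressors (mean 0.028, median -0.045, 0.374; 1 member over the list alone), drivers (0.16, -0.038, 0.628) and iron handling (0.066, 0.0051, 0.559) were not called by camera. Adjusted over the list alone 2 fibroblast, 1 melanocyte and 1 alternatively activated macrophage genes passed. Fry and the exact permutation over tumours called 0 lists. Of the 18 lists 8 were called in each of 20 fits without 1 library. The interferon gamma call ended without IgG 2 (-0.28), IgG 4, anti-PD-1 1 (-0.34) and anti-PD-1 2 (-0.20, adjusted p = 0.394), with -0.85 without anti-PD-1 5. MHC class I ended without IgG 2 (-0.14), IgG 4 and anti-PD-1 1, 2 and 4 (-0.16, -0.215 and -0.23), with -0.64 and -0.625 without anti-PD-1 3 and 5. Mitochondrial-encoded genes ended without anti-PD-1 2 (0.092, 0.0784), with 0.12 without IgG 3. Without anti-PD-1 3 the calls of mast cell, cholesterol (-0.056), fatty acid (-0.074), lysosome, keratinocyte and adipocyte genes ended. Cholesterol and lysosome also ended without anti-PD-1 2, cholesterol without IgG 1 and fatty acid without IgG 4, and cholesterol stood at -0.16 without IgG 2. Red blood cell genes ended without IgG 4 (-0.94), IgG 5 (-0.74) and anti-PD-1 5, and adipocyte genes without these and anti-PD-1 1, with 1.62 without anti-PD-1 2. Chemokines stood at 0.495 without IgG 1 and hypoxia and glycolysis at -0.17 without anti-PD-1 1, both still called.

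Combination tumours differed from IgG tumours in 774 genes, 356 higher and 418 lower. Postn rose by 1.5 ± 0.181 on the log2 scale (± SE, edgeR adjusted p = 0.00092), from 18.1 ± 3.52 to 51.1 ± 7.88 CPM (mean ± SD, n = 5 each). It is gene ENSMUSG00000027750 at 54361109 to 54391037 on chromosome 3 of GRCm38. Mgl2, a lectin of alternatively activated macrophages (ENSMUSG00000040950, chromosome 11, 70130329 to 70137550), rose by 2.73 ± 0.397 (0.0038), from 0.431 ± 0.131 to 2.87 ± 1.43 CPM. Xist, the noncoding RNA of the inactive X chromosome (ENSMUSG00000086503, chromosome X, 103460366 to 103483254), rose by 2.09 ± 0.302 (0.0038), from 2.21 ± 1.11 to 9.43 ± 2.43 CPM, and the strand of its reads is unknown. Ahnak, a large scaffold protein gene, rose by 1.12 ± 0.19 (0.012) and Hspb1, a small heat shock protein that restrains iron uptake, by 2.19 ± 0.365 (0.012). The muscle genes Casq1 (2.5 ± 0.361, 0.0038), Pvalb (5.38 ± 0.803, 0.0054) and Ldb3 (3.81 ± 0.64, 0.012) were also among the 8 with the smallest p. The genes that fell with the smallest p were Dera (-0.46 ± 0.0805), Pdk3 (-0.61 ± 0.109), the hypoxia-induced mitophagy receptor Bnip3l (-0.64 ± 0.115), Rnf126 (-0.76 ± 0.136), the mitochondrial genes Mrpl45 (-0.32), Prelid1 (-0.35) and Lonp1 (-0.33), all with adjusted p = 0.012, and malic enzyme Me2 (-0.65 ± 0.119, 0.013). Changes were larger upward, with a median log2 change of 1.64 among genes that rose and -0.36 among genes that fell, and 330 rose and 81 fell by at least 1.5-fold.

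The 774 calls came with 3741 genes at an unadjusted p under 0.05, and DESeq2 called 1423, limma voom 980 and limma on log2(TPM + 1) 621. All 774 kept their direction in each fit without 1 library, which is likely for genes chosen by their p in the same libraries. The count itself depended on single libraries: it was 5 without IgG replicate 3, 67 without IgG 5, 202 without IgG 1, and 190, 307, 366, 147 and 72 without combination 1, 2, 3, 4 and 5. Postn, Mgl2, Casq1, Pvalb and Xist are the 5 genes called without IgG replicate 3, with Postn at 1.43 (adjusted p = 0.0068) and Mgl2 at 2.58 (0.023), and they are the 5 of 58 named genes that passed in all 20 such fits. The split of 356 higher and 418 lower moved with the scaling, to 306 and 217 with DESeq2 size factors and to 368 and 112 with library totals, and it was 509 and 112 on log2(TPM + 1).

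**Figure D2:**
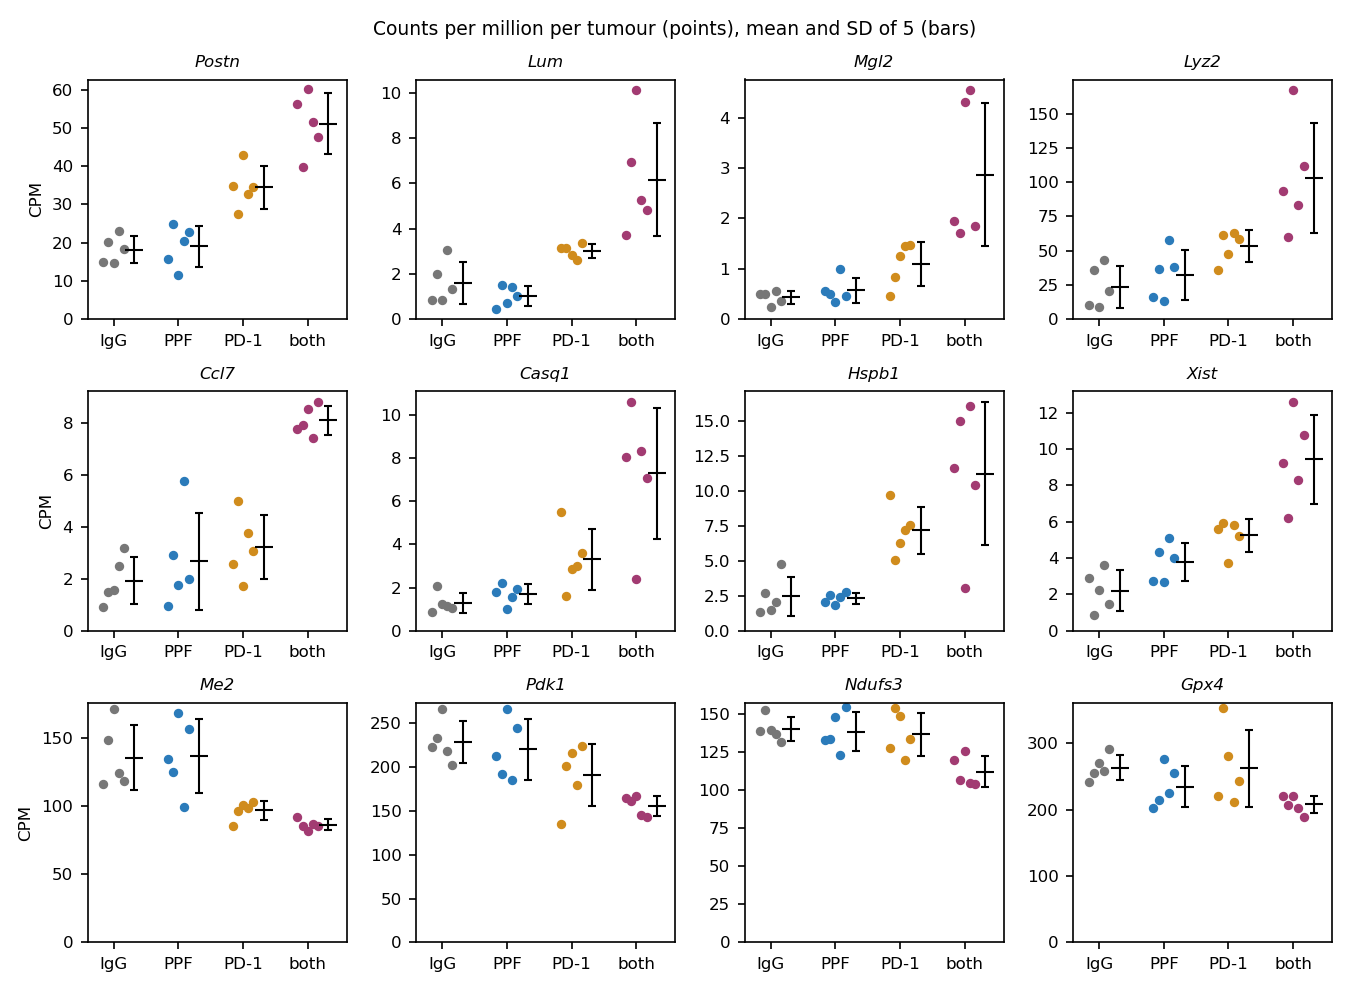
CPM (vertical axis) of 12 named genes in each tumour (points) by group, with the mean and SD of 5 as bars. Postn, Mgl2, Lyz2, Ccl7, Casq1, Hspb1 and Xist had their highest group mean in the combination, and Me2, Pdk1, Ndufs3 and Gpx4 their lowest.

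Macrophage lists were called higher in the combination than in IgG tumours, and skeletal muscle markers were higher beside them (mean log2 change 4.41; 16 of 19 members over the list alone). In the macrophage and monocyte list all 20 members were higher, with a mean log2 change of 1.97 (camera adjusted p = 1.01e-16, adjusted p = 0.16 with an estimated correlation), and 11 members rose, 18 adjusted over the list alone. Lyz2, the lysozyme of myeloid cells (ENSMUSG00000069516, chromosome 10, 117277331 to 117282321), rose by 2.13 ± 0.46 (edgeR adjusted p = 0.024), from 23.6 ± 15.2 to 103 ± 40.2 CPM. Mrc1 rose by 1.72 ± 0.4 (0.026) and Ly6c2, a marker of inflammatory monocytes, by 2.26 ± 0.54 (0.027). In the chemokine list (1.73, 1.46e-10, 0.16; 8 rose, 11 over the list alone) the monocyte attractants Ccl7 (2.07 ± 0.395, 0.015, 1.93 to 8.12 CPM), Ccl12 (1.74, 0.022) and Ccl2 (1.5, 0.028) rose. Alternatively activated macrophage genes (2.59, 2.93e-08, 0.16; 3 rose, 8 over the list alone) included Mgl2, Mrc1 and Stab1 (1.08, 0.032). Pro-inflammatory macrophage genes (1.26, 6.55e-05, 0.21; 2 rose, 3 over the list alone) included Ccl2 and the costimulator Cd80 (1.37, 0.039). Dendritic cell genes (1.13, 0.000306, 0.25; 2 rose, 3 over the list alone) included Naaa (0.81, 0.02) and Wdfy4 (1.80, 0.031), which serves cross-presentation. Mast cell genes (2.89, 6.25e-05, 0.16; 3 rose, 4 over the list alone) included the proteases Mcpt4 (3.27, 0.027), Tpsb2 (2.77, 0.031) and Cma1 (3.24, 0.039), the last from 0.0599 to 0.586 CPM. Tyrobp (1.67, 0.0487), a myeloid and NK cell adaptor named after its value was seen, rose in the NK cell list, which had too few members to test. Without IgG replicate 3 only Mgl2 of these genes kept its call, and with the muscle list score as a covariate none did, Mgl2 standing at 2.60 (0.0517) and Lyz2 at 1.97 (0.114).

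Lymphocyte and interferon lists were called higher with few single genes past the threshold. Cytotoxic effector genes (1.80, camera adjusted p = 6.25e-05, 0.32 with an estimated correlation) had 1 that rose, the granzyme Gzma (3.66 ± 1.05, edgeR adjusted p = 0.049), from 0.0434 to 0.575 CPM. T cell genes (1.21, 0.000572, 0.34) and checkpoint genes (1.17, 0.00151, 0.32) had 0, and 0 and 2 adjusted over the list alone. Cd8a measured 1.45 ± 1.16 CPM in combination and 0.591 ± 0.409 in IgG tumours (1.28, 0.32), Prf1 stood at 1.68 (0.21), Pdcd1 at 1.37 (0.32), Gzmb at 1.01 (0.5), Ifng at 0.31 (0.89) and Cd274, which encodes PD-L1, at 0.86 (0.11). Type I interferon response (1.15, 2.93e-08, 0.32; 2 rose, 4 over the list alone) included Ifi44 (2.11, 0.02) and Oas2 (1.74, 0.04), and interferon gamma response (0.99, 1.84e-05, 0.38) had 0 that rose with all 22 members higher. MHC class I presentation (0.50, 0.0108, 0.56; 1 rose, 2 over the list alone) held H2-Q7 (1.82, 0.026), which shares reads with its paralogs, and MHC class II presentation (0.96, 0.0144, 0.43) and neutrophil genes (0.78, 0.0305, 0.33) had 0. Plasma cell genes (1.05, 0.0144, 0.22; 1 rose, 1 over the list alone) held Ighm (2.60, 0.021), and TNF and NF-kappaB targets (0.49, 0.00852, 0.33; 3 rose and 1 fell over the list alone) held Csf1, the macrophage growth factor (0.71, 0.049), and Ier3, which fell (-1.35, 0.044). B cell (1.22, 0.0988) and regulatory T cell genes (0.82, 0.143) were not called by camera, while the exact permutation over tumours called both (adjusted p = 0.032 and 0.04). The permutation called none of the lists that camera called in this paragraph: TNF targets 0.056, checkpoint, type I interferon and plasma cell 0.069 each, cytotoxic 0.071, T cell 0.11, interferon gamma 0.13, neutrophil 0.16, MHC class II 0.21 and MHC class I 0.24. Without IgG replicate 3 none of the single genes of these lists kept its call, and with the muscle list score as a covariate none did either. The list call ended without IgG 5, combination 1 (0.32) and combination 3 for MHC class I, without IgG 5 and combination 1 for MHC class II, and without combination 3 for TNF targets. Neutrophil genes lost it in 15 of 20 fits, with 0.49, 0.44 and 0.45 without IgG 1, IgG 3 and combination 3.

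The fibroblast list was called higher in the combination beside lists of muscle, skin and fat markers. The fibroblast list (0.90, camera adjusted p = 8.79e-10, 0.23 with an estimated correlation; 6 rose, 11 over the list alone) held Postn, Lum, a collagen-binding proteoglycan (1.94 ± 0.364, edgeR adjusted p = 0.013, 1.6 to 6.16 CPM), and Fap, the fibroblast activation protein (1.22 ± 0.285, 0.026). Endothelium (0.29, 0.0108, 0.39; 1 rose, 1 over the list alone) held the angiopoietin receptor Tek (1.72, 0.029). Skeletal muscle stood 4.41 higher (1.23e-06, 0.33; 8 rose, 16 over the list alone), with Ckm, the muscle creatine kinase, from 1.95 ± 0.747 to 35.8 ± 16.5 CPM (4.19 ± 0.74, 0.013). Keratinocyte genes were called higher (0.00207, 0.40; 0 rose, 12 over the list alone), with 6 of the list at 0 in all IgG tumours, and adipocyte genes too (1.83, 0.00321, 0.33; 1 rose, 7 over the list alone), with the lipase Lpl at 1.69 (0.024). Red blood cell genes were lower (-3.07, 0.00178, 0.33; 2 fell, 7 over the list alone), with the anion exchanger Slc4a1 at -4.34 (0.034). Melanocyte lineage genes were higher (0.29, 0.00163, 0.32) with 0 past the threshold, and Mitf, their master regulator, stood at 0.57 (0.3). With the muscle list score as a covariate, which is correlated with the groups, 8 genes were called, 7 of them among the 774: Postn (1.23), Xist (2.30), Igfbp6, Lrp1, Mmp23, F2rl1, Vcan and Cmah, named because the count was small. The exact permutation over tumours did not call endothelium and adipocyte (adjusted p = 0.071 each) and keratinocyte genes (0.067), and called the other lists of this paragraph. Without IgG replicate 3 only Postn, Casq1 and Pvalb of the genes in these lists kept their calls.

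Glycolysis and respiratory chain lists were called lower in the combination by modest amounts. Hypoxia and glycolysis (-0.47, camera adjusted p = 1.46e-10, 0.22 with an estimated correlation) had 9 that fell, 17 over the list alone. Ldha, lactate dehydrogenase A (ENSMUSG00000063229, chromosome 7, 46841475 to 46855627), fell from 3180 ± 223 to 2470 ± 123 CPM (-0.37 ± 0.0748, edgeR adjusted p = 0.018), Eno1 from 5020 ± 366 to 3870 ± 225 (-0.38, 0.019) and Pdk1, which inhibits pyruvate dehydrogenase, from 229 ± 23.8 to 156 ± 11.4 (-0.56, 0.021). Respiratory chain complex I (-0.17, 7.54e-07, 0.33; 4 fell, 11 over the list alone) held Ndufs3 (-0.32, 0.03), Ndufa10 (-0.34, 0.031) and Ndufv2 (-0.23, 0.041). Its median of -0.15 lay at percentile 31 of random lists of like transcript length and expression. Complexes II to V (-0.18, 1.46e-10, 0.32; 6 fell, 19 over the list alone), with a median of -0.19 at percentile 3.2 of such lists, held the ATP synthase genes Atp5g1 (-0.38, 0.024) and Atp5g3 (-0.32, 0.026) and Cox6b1 (-0.25, 0.026). The random lists fell too, with medians of -0.13 for complex I and -0.14 for complexes II to V. None were drawn for hypoxia and glycolysis, so a fall particular to that list was not tested. Fatty acid synthesis (-0.15, 0.0305, 0.32; 2 fell, 4 over the list alone) held Me1 (-0.43, 0.028) and Dgat2, which makes triglyceride (-1.08, 0.039), and cholesterol synthesis (-0.12, 0.0119, 0.35) had 0. JNK and AP-1 genes (-0.34, 0.0108, 0.47; 2 rose and 4 fell over the list alone) held the kinases Map2k4 (-0.25, 0.039) and Map2k7 (-0.24, 0.049) and Ier3, all of which fell, against Egr3, which rose (1.03, 0.0437), and Jun stood at -0.58 (0.24). Mitochondrial-encoded (-0.021, 0.861), lysosome (-0.031, 0.41), ATF4 and ER stress (-0.15, 0.745), cell cycle (0.06, 0.264) and p53 target genes (0.018, 0.256) were not called by camera, though in the last Eda2r rose (1.56, 0.0315) and the cell cycle inhibitor Cdkn1a fell (-1.49, 0.0461), both named after their values were seen. The exact permutation over tumours called hypoxia and glycolysis (adjusted p = 0.032) and both respiratory chain lists (0.04), and not JNK and AP-1 (0.067), fatty acid (0.069) or cholesterol genes (0.16). Without IgG replicate 3 none of these genes kept its call. With the muscle list score as a covariate none did either, and the 8 genes called in that fit were all higher. The camera call ended without IgG 1, 3 and 4 for fatty acid synthesis, without IgG 1 for cholesterol synthesis and without IgG 2 for JNK and AP-1 genes (-0.21).

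Ferroptosis lists were not called by camera in combination against IgG tumours, and single members moved both ways. The suppressor list (mean -0.0098, median -0.11, camera adjusted p = 0.0583, 0.22 with an estimated correlation) had 21 of 25 members lower and 1 that rose, Hspb1. Gpx4 (ENSMUSG00000075706, chromosome 10, 80047166 to 80056439) measured 208 ± 12.9 CPM against 263 ± 18.9 in IgG tumours (mean ± SD, n = 5 each, -0.34 ± 0.113, edgeR adjusted p = 0.078). The driver list (mean 0.25, median -0.11, 0.113) had 18 of 23 members lower, and the glutaminase Gls2 (-0.84, 0.0299) and the anion channel Vdac3 (-0.27, 0.0347), named after their values were seen, fell. Iron handling (mean 0.09, median -0.0074, 0.925) had the siderophore binder Lcn2 higher (2.56, 0.0495) and ferrochelatase Fech lower (-0.34, 0.0449), chosen the same way. Hmox1 measured 92.4 ± 26.2 CPM against 140 ± 32.7 (-0.60, 0.24), Fth1 stood at -0.24 (0.14), Slc7a11 at -0.13 (0.85), Tfrc at -0.12 (0.58) and Acsl4 at -0.05 (0.88). NRF2 targets were called lower (-0.18, 0.00287, 0.16; 4 fell, 5 over the list alone), with the pentose phosphate enzymes G6pdx (-0.69 ± 0.143, 0.019) and Tkt (-0.32, 0.027) and with Me1 (-0.43, 0.028). Fry, a test of movement one way, called the suppressor list (0.0056) and 11 others against IgG, and fry for movement in either direction gave adjusted p = 0.017 for suppressors, 0.00051 for drivers and 0.00029 for iron handling. The exact permutation over tumours gave 0.83, 0.18 and 0.071 for these lists. That test uses the list mean, and for suppressors the 21 lower members are offset in the mean by Hspb1 at 2.19. Without IgG replicate 3 none of these genes kept its call. With the muscle list score as a covariate none did either, Hspb1 included.

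**Figure D3:**
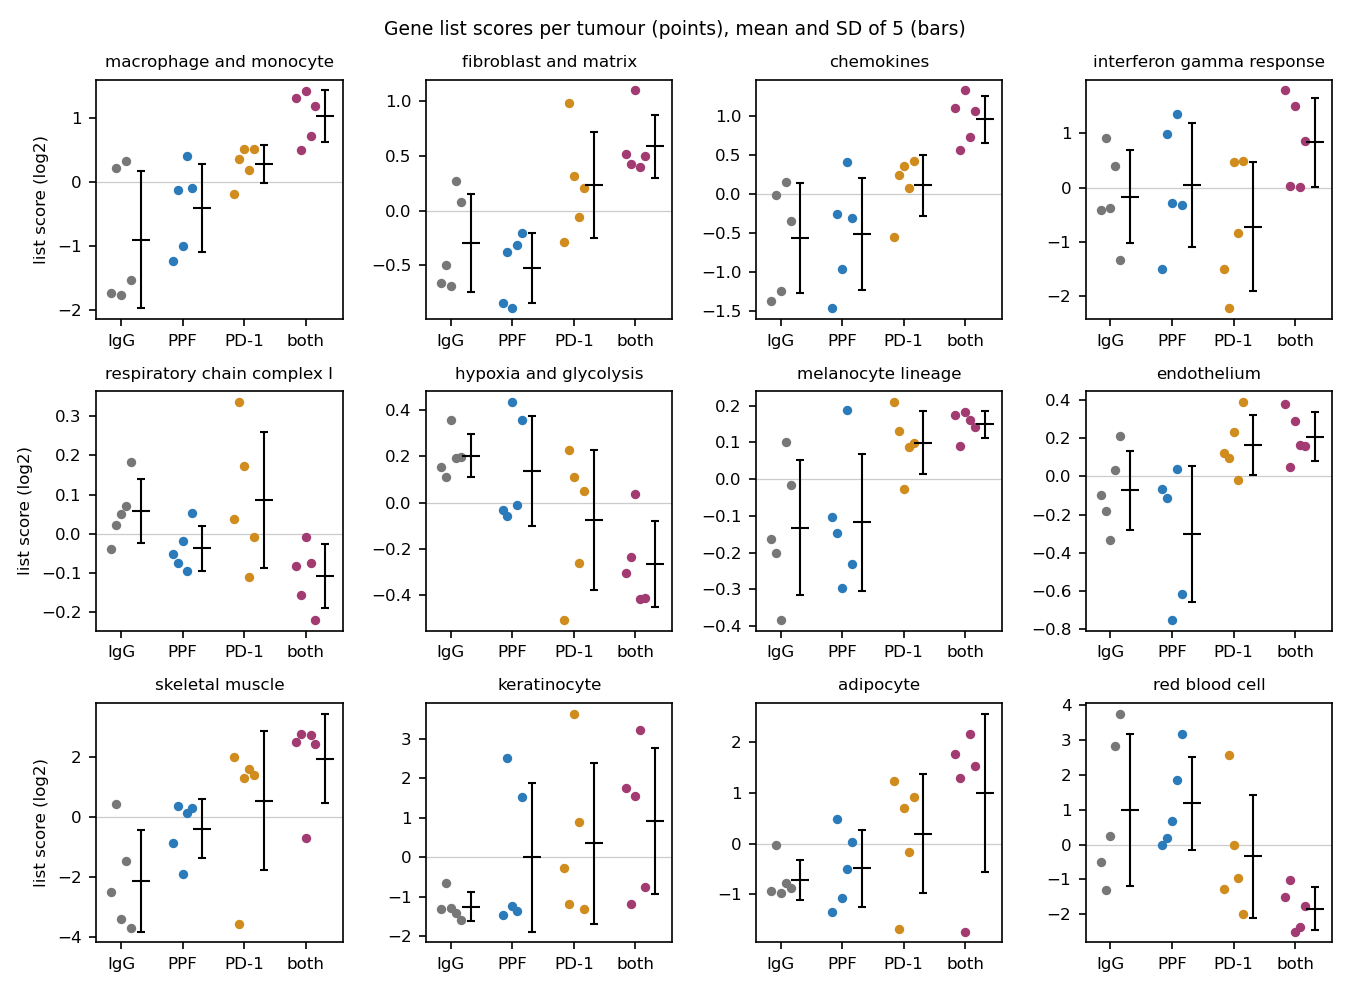
Gene list scores (vertical axis, mean log2 CPM of the members centred on all libraries) of 12 lists in each tumour (points) by group, with the mean and SD of 5 as bars. Macrophage, fibroblast and chemokine scores of the 5 combination tumours lay above all 5 IgG tumours, while interferon gamma and keratinocyte scores overlapped.

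Added to propafenone, anti-PD-1 changed 616 genes, 265 higher and 351 lower. Postn rose by 1.42 ± 0.181 (log2 ± SE, edgeR adjusted p = 0.0019), from 19 ± 5.43 to 51.1 ± 7.88 CPM (mean ± SD, n = 5 each). Lum (ENSMUSG00000036446, chromosome 10, 97565128 to 97572703) rose by 2.59 ± 0.374 (0.0047), from 1.02 ± 0.455 to 6.16 ± 2.48 CPM, and Dnaja4, a heat shock cochaperone (ENSMUSG00000032285, chromosome 9, 54698873 to 54716315), by 2.48 ± 0.358 (0.0047), from 0.374 ± 0.16 to 2.1 ± 0.861 CPM. Lama2, a laminin (1.02), Hspb1 (2.27), Csgalnact1, which starts chondroitin sulfate chains (1.38), Mgl2 (2.33) and Pvalb (4.57) rose with adjusted p = 0.013. Lypla1 (-0.36, 0.013), Me2 (-0.66, 0.018), Sbf2 (-0.37, 0.019), Pdpr, the pyruvate dehydrogenase phosphatase regulator (-0.84, 0.021), and Mrpl45 (-0.31), Dpf1 (-1.29), Homer1 (-0.68) and Ganc (-0.49), each at 0.022, fell. The median log2 change was 1.32 among genes that rose and -0.46 among genes that fell, and 240 rose and 110 fell by at least 1.5-fold. At an unadjusted p under 0.05 stood 3681 genes, and DESeq2 called 1466, limma voom 937 and limma on log2(TPM + 1) 454. Library totals gave 258 higher and 89 lower, and DESeq2 size factors 231 and 207. The count was 4 without propafenone replicate 3 (Postn, Dnaja4, Lum and Ephx2) and 230, 1882 and 23 without propafenone 1, 4 and 5, it was 133, 127, 50, 85 and 27 without combination 1, 2, 3, 4 and 5, and it was 392, 405, 959 and 405 without IgG 4, IgG 5, anti-PD-1 2 and anti-PD-1 5. Of 43 named genes Postn, Dnaja4 and Lum passed in all 20 fits.

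Fibroblast and macrophage lists were called higher over propafenone. In the fibroblast list (1.12, camera adjusted p = 1.37e-13, adjusted p = 0.21 with an estimated correlation) 13 rose, 17 adjusted over the list alone, with the collagen Col3a1 from 52.2 ± 22.8 to 283 ± 156 CPM (2.44 ± 0.505, edgeR adjusted p = 0.026). Endothelium (0.51, 9.13e-06, 0.31; 2 rose, 12 rose and 1 fell over the list alone) held Tek (2.17, 0.022) and Pecam1 (0.76, 0.031). Macrophage genes (1.44, 1.37e-13, 0.21; 2 rose, 19 over the list alone) held Lyz2 (1.67) and Mrc1 (1.44), both at 0.047, and alternatively activated genes (1.99, 2.64e-06, 0.21; 4 rose, 7 over the list alone) held Stab1 (1.22, 0.028) and Retnla (6.36, 0.042), the latter at 0.0359 CPM after propafenone. Chemokines (1.69, 3.62e-10, 0.21; 3 rose, 9 over the list alone) held the eosinophil attractant Ccl11 (1.99, 0.026), the neutrophil attractant Cxcl5 (4.54, 0.03) and Ccl7 (1.60, 0.033). Mast cell genes (2.35, 0.000177, 0.21; 1 rose, 5 over the list alone) held Mcpt4 (2.80, 0.045), dendritic cell genes (0.92, 0.000389, 0.31; 1 rose, 4 over the list alone) Naaa (0.68, 0.037) and neutrophil genes (0.93, 0.0195, 0.44; 1 rose, 2 over the list alone) the receptor Csf3r (1.77, 0.049). T cell genes (0.72, 0.00853, 0.5; 1 rose, 1 over the list alone) held Thy1 (0.96, 0.033), which the fibroblast list also holds, plasma cell genes (1.21, 0.0195, 0.27; 1 rose, 1 over the list alone) Ighm (2.81, 0.022) and MHC class I genes (0.54, 0.00799, 0.53; 1 rose, 2 over the list alone) H2-Q7 (1.83, 0.03). Called with 0 that rose were pro-inflammatory macrophage (1.18, 0.000105, 0.21; 3 over the list alone), type I interferon (0.72, 0.000149, 0.48), interferon gamma (0.79, 0.000468, 0.5), cytotoxic (1.18, 0.00171, 0.45), MHC class II (0.95, 0.00937, 0.48), checkpoint (0.70, 0.00985, 0.45; 1 over the list alone), melanocyte (0.27, 0.00389, 0.45) and mitochondrial-encoded genes (0.17, 0.0152, 0.52). Muscle markers moved with the matrix genes (2.36, 6.53e-06, 0.45; 4 rose, 13 over the list alone), with Ckm at 3.40 (0.026) and Casq1 at 2.10 (0.013). Adipocyte genes did too (1.53, 0.00416, 0.45; 1 rose, 5 over the list alone), with Lpl at 1.37 (0.047), and red blood cell genes were lower (-3.28, 0.000652, 0.44; 1 fell, 7 over the list alone), with Slc4a1 at -4.47 (0.037). The exact permutation over tumours called fibroblast, endothelium, macrophage, alternatively activated, chemokine, mast cell and red blood cell genes (adjusted p = 0.032 each) and mitochondrial-encoded genes (0.049). It did not call the other 14 lists of this paragraph, with 0.068 for neutrophil, 0.071 for dendritic cell, plasma cell and muscle, 0.084 for pro-inflammatory macrophage and 0.095 for melanocyte genes. It gave 0.16 for cytotoxic, checkpoint and adipocyte, 0.19 for type I interferon and MHC class II, 0.25 for MHC class I, 0.27 for interferon gamma and 0.28 for T cell genes. Without propafenone replicate 3 only Postn and Lum of the genes in these lists kept their calls. Without propafenone 1 the calls of T cell, checkpoint, plasma cell, neutrophil (0.32), interferon gamma (0.41), type I interferon (0.38), MHC class I (0.29) and MHC class II genes ended. T cell (0.48) and both MHC lists ended without combination 1, MHC class I without combination 3, and mitochondrial-encoded genes without propafenone 2. Neutrophil genes lost their call in 13 of 20 fits, combination 3 (0.51) among them, and adipocyte genes stood at 2.42 without combination 3.

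Glycolysis genes were lower over propafenone as well (-0.41, camera adjusted p = 3.32e-08, 0.33 with an estimated correlation; 4 fell, 13 over the list alone). Pdk1 (-0.50, edgeR adjusted p = 0.032), the mitophagy gene Bnip3 (-0.70, 0.04) and the angiogenic factor Vegfa (-1.10 ± 0.292, 0.045), from 380 ± 186 to 177 ± 39 CPM (mean ± SD, n = 5 each), fell. Complexes II to V (-0.11, 2.28e-05, 0.48; 1 fell, 9 over the list alone) held Uqcrfs1 (-0.35, 0.031) and complex I (-0.071, 0.0213, 0.61; 1 fell, 4 over the list alone) held Ndufs3 (-0.30, 0.042). Neither these lists nor the glycolysis list were set against random lists of like transcript length and expression over propafenone. JNK and AP-1 genes (-0.42, 0.00344, 0.48; 2 fell, 5 over the list alone) held Map2k4 (-0.25, 0.045) and Ier3 (-1.36, 0.046), and Ier3 also fell in the TNF and NF-kappaB list, called higher (0.37, 0.0336, 0.48; 1 rose and 1 fell over the list alone). Ferroptosis suppressors (mean 0.076, median -0.058, 0.397), drivers (0.18, -0.094, 0.234), iron handling (0.16, -0.023, 0.707) and NRF2 targets (-0.05, 0.367) were not called by camera, though Hspb1 and the iron genes Lcn2 (3.14, 0.0328), Steap4 (1.60, 0.0332) and Steap1 (0.68, 0.0446) rose and Mboat2 (-0.35, 0.0432), G6pdx (-0.70, 0.0245) and Me1 (-0.49, 0.0261) fell, all but Hspb1 named after their values were seen. The exact permutation over tumours called iron handling (adjusted p = 0.032) and ferroptosis suppressors (0.049) here, both for a higher list mean. That mean rests on few members: 17 of 25 suppressors were lower beside Hspb1 at 2.27, and 16 of 30 iron genes were lower beside Lcn2, Steap4 and Steap1. Of the lists that camera called in this paragraph the permutation called complexes II to V (0.049), and not hypoxia and glycolysis (0.071), complex I (0.22), JNK and AP-1 (0.16) or TNF targets (0.16). Fry for movement in either direction gave adjusted p = 4.8e-05 for iron handling, 0.011 for suppressors and 0.007 for drivers. Of the panel Gpx4 stood at -0.18 (0.35), Hmox1 at -0.40 (0.44), Slc7a11 at 0.46 (0.42), Cd8a at 1.06 (0.42) and Cd274 at 0.51 (0.35). Without propafenone replicate 3 none of these genes kept its call. The complex I list call ended without propafenone 5 (-0.044), combination 2 and combination 5 (-0.043). TNF targets ended without propafenone 1 (0.20), propafenone 2, anti-PD-1 3, combination 1 and combination 3, and JNK and AP-1 genes stood at -0.26 without propafenone 3.

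Added to anti-PD-1, propafenone gave no gene past the threshold. Tmem126a, a complex I assembly factor, stood at -0.33 ± 0.0642 (log2 ± SE), the ATP synthase gene Atp5c1 at -0.29 ± 0.0574 and the complex I gene Ndufc2 at -0.31 ± 0.0625, all with edgeR adjusted p = 0.26. Naaa stood at 0.76, Wdfy4 at 1.78 and the integrin Itgb7 at 1.72, all at 0.45. In the panel Gpx4 stood at -0.33 (0.45), Cd274 at 0.86 (0.45), Cd8a at 1.44 (0.55), Prf1 at 1.5 (0.55), Ifng at 2.16 (0.55) and Hmox1 at -0.37 (0.69). edgeR called 0 genes, with 1552 at an unadjusted p under 0.05, and limma voom 0. DESeq2 called 7, Krt77, Atp5c1, Ndufc2, Naaa, Rps27l, Tmem126a and Ighm, and limma on log2(TPM + 1) and edgeR on these groups alone called 1, Ighm, at 2.06 (0.0083) and 2.78 (0.026), all named after their values were seen. In simulated data with genes drawn independently, the test recovered 46% of genes changed 1.5-fold and 60% of genes changed 2-fold.

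Camera called 26 lists for propafenone added to anti-PD-1. Complexes II to V were lower in all 39 members (-0.21, camera adjusted p = 2.07e-25, 0.19 with an estimated correlation), 28 of them past the threshold adjusted over the list alone, with Cox6b1 at -0.25 and Cox7c at -0.27. Complex I was lower in all 37 (-0.19, 8.96e-17, 0.19; 14 over the list alone), with Ndufv2 at -0.25 and Ndufa10 at -0.31, and mitochondrial-encoded genes in all 13 (-0.21, 1.93e-05, 0.29), with mt-Nd1 at -0.24. Random lists of like transcript length and expression were drawn only for combination against IgG. Their medians there were -0.13 for complex I and -0.14 for complexes II to V. A fall particular to the respiratory chain was therefore not tested here. Interferon gamma response was higher in all 22 (1.53, 1.17e-14, 0.24; 6 over the list alone), with Ciita, which drives MHC class II genes, at 2.22 and Gbp5 at 1.92. Type I interferon response (0.86, 3.12e-10, 0.24; 1 over the list alone), with Ifi44 at 1.63, MHC class I (0.87, 3.82e-08, 0.29), with H2-Q7 at 1.27, and MHC class II (1.32, 3.69e-05, 0.27), with H2-Ob at 1.83, were called higher. Cytotoxic genes (1.62, 1.75e-06, 0.24), with Ccl4 at 1.3 and Gzmk at 2.82, checkpoint genes (0.96, 0.000127, 0.24), with Havcr2 at 0.51, and T cell genes (0.80, 0.00247, 0.45), with Trbc1 at 1.73, were called higher. So were dendritic cell genes (1.08, 8.17e-07, 0.19; 2 over the list alone), with Clec9a at 1.68, chemokines (0.93, 4.55e-09, 0.19; 2), with Ccl2 at 1.28, macrophage genes (0.76, 1.59e-08, 0.24; 4), with Ly6c2 at 1.84, alternatively activated (1.13, 1.32e-05, 0.22; 2), with Chil3 at 2.32, pro-inflammatory (0.92, 2.61e-05, 0.19; 2), with Il12b at 3.91, mast cell (1.51, 6.05e-05, 0.19), with Cma1 at 1.67, and B cell genes (1.57, 0.0136, 0.19), with Bank1 at 2.37. Fibroblast (0.37, 3.69e-05, 0.34), cell cycle (0.12, 0.000846, 0.44), with Top2a at 0.29, and TNF and NF-kappaB genes (0.29, 0.0477, 0.47), with Icam1 at 0.83, were called higher, and lysosome (-0.12, 3.69e-05, 0.24), with Npc2 at -0.19, hypoxia and glycolysis (-0.19, 4.21e-05, 0.34), with Pkm at -0.21, and NRF2 targets (-0.14, 0.0064, 0.19), with Gstm1 at -0.34, lower. Muscle (1.40, 1.32e-05, 0.36), with Casq1 at 1.14, and adipocyte markers (0.75, 0.0488, 0.48), with Adipoq at 1.63, were higher beside them and red blood cell markers (-1.64, 0.0219, 0.47), with Hba-a2 at -2.52, lower. Fry called 2, complexes II to V and mast cell genes (0.049 each). The exact permutation over tumours called 0, with 10 lists at an unadjusted p under 0.05 and 4 without overlap of the groups. So few lists at its smallest possible p cannot pass the adjustment, so this 0 does not exclude a shift. Ferroptosis suppressors (-0.037, 0.133), drivers (mean 0.086, median -0.10, 0.121) and iron handling (0.025, 0.683) were not called by camera. Without anti-PD-1 2 camera called 21 lists, and the calls of T cell (0.36), B cell, muscle (0.35), adipocyte (0.20) and red blood cell genes (-0.94) ended. Mitochondrial-encoded genes stood then at -0.11, mast cell genes at 0.955 and hypoxia and glycolysis at -0.12, all still called. T cell genes also ended without combination 1, TNF targets in 9 of 20 fits, with 0.097 and 0.47 without anti-PD-1 1 and 3, and adipocyte genes in 15, with 1.65 and 0.415 without combination 3 and 4. Without anti-PD-1 1 fibroblast genes stood at 0.24 and hypoxia and glycolysis at -0.30, and without anti-PD-1 3 NRF2 targets at -0.082 and lysosome genes at -0.078.

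The interaction, the question of synergy, gave no gene past the threshold. Dnaja4 stood at 1.78 ± 0.485 (log2 ± SE), Lum at 1.68 ± 0.506 and Lama2 at 0.76 ± 0.231, and lower were Ankfn1 (-1.19), Usp54 (-0.40) and Bdh1 (-0.42), all with edgeR adjusted p = 0.99. edgeR called 0 genes, with 482 at an unadjusted p under 0.05, limma voom 0, both TPM fits 0, and DESeq2 2, Pcdhga10 and Krt1, named after their values were seen. Camera called 17 lists: interferon gamma response at 1.34 (camera adjusted p = 5.03e-10, 0.62 with an estimated correlation), with Ciita at 1.93 and Irf1 at 0.96, MHC class I at 0.92 (1.31e-07, 0.62), MHC class II at 1.31 (0.000287, 0.62), with H2-DMb2 at 1.28, and fibroblast genes at 0.59 (6.25e-08, 0.62), with Col6a1 at 0.76, stood above the sum of the single effects. Complexes II to V at -0.14 (1.43e-11, 0.62), with Uqcrc2 at -0.32, and complex I at -0.097 (4.56e-05, 0.63), with Ndufs1 at -0.22, stood below it. Random lists of like transcript length and expression were not drawn for the interaction. Red blood cell genes were called too, at -1.85 (0.00912, 0.63) with all 7 members lower, though not without IgG 2 or anti-PD-1 2 (-1.16). Macrophage genes at 0.23 (0.11), muscle at -0.65 (0.636), ferroptosis suppressors at 0.049 (0.928), drivers at 0.014 (0.267) and iron handling at 0.092 (0.928) were not called by camera. Of the 17 lists 8 were called in each of 20 fits without 1 library, MHC class II ended without IgG 2 and complex I without anti-PD-1 2 (-0.045), with -0.146 without anti-PD-1 4. Without IgG replicate 2 camera called 11 lists and without anti-PD-1 replicate 2 it called 9, fry called 0, and 0 members of any called list passed when adjusted over the list alone. In simulated data with genes drawn independently, the test recovered 12% of genes with an interaction of 1.5-fold and 48% of 2-fold.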

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

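The tests against the muscle score, the share of tumour cells and the libraries rich in haemoglobin were chosen after the results were seen. Values of 1 tumour far from the other 4 of its group were found in 15 of 328 groups of 5 values, where 16.4 are expected by chance. List scores were B cell -1.56 in IgG 5 (others -0.0734 to 0.178), mast cell -1.68 in anti-PD-1 2 (0.314 to 0.685) and 0.93 in combination 2 (1.52 to 1.61), fatty acid synthesis -0.25 in anti-PD-1 3 (-0.0525 to 0.0238), and fibroblast 1.1 in combination 3 (0.402 to 0.516). Skeletal muscle stood at -3.56 in anti-PD-1 2 (1.32 to 2.01) and -0.709 in combination 3 (2.44 to 2.8), and adipocyte at -0.0208 in IgG 2 (-0.978 to -0.778) and -1.73 in combination 3 (1.28 to 2.15). CPM values were Hmox1 139 in combination 3 (76.7 to 85.2), Tfrc 758 in propafenone 3 (634 to 668), Ifng 0.502 and Mitf 920 in combination 1 (0.0742 to 0.142 and 608 to 658), Ldb3 0.775 in IgG 2 (0.131 to 0.258) and Lama2 5.85 in combination 2 (4.71 to 4.82).

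The interaction of 17 lists was called by camera, a difference of the propafenone effect between backgrounds. Mean log2 values were interferon gamma 1.34, MHC class II 1.31, B cell 1.37, cytotoxic 0.997, MHC class I 0.918, chemokines 0.888, dendritic cell 0.859, pro-inflammatory macrophage 0.835, fibroblast 0.591, checkpoint 0.496, type I interferon 0.429 and endothelium 0.269. Lower were red blood cell -1.85, complexes II to V -0.139, hypoxia and glycolysis -0.123, complex I -0.097 and lysosome -0.0944. With an estimated correlation the adjusted p was 0.62 to 0.8 for each. In fits without 1 library the call ended 11 times for B cell, 9 for checkpoint, 9 for hypoxia and glycolysis, 8 for type I interferon, 6 for cytotoxic, 2 for lysosome (propafenone 4, anti-PD-1 2), 2 for red blood cell (IgG 2, anti-PD-1 2), and 1 for MHC class II (IgG 2) and complex I (anti-PD-1 2). The type I interferon value without propafenone 1 was 0.0802, and the cytotoxic value without IgG 4 was 0.599. Checkpoint stood at 0.192 without IgG 2 and 0.767 without IgG 5. Hypoxia and glycolysis stood at -0.0491 without propafenone 3 and -0.229 without anti-PD-1 1. The lowest values still called were pro-inflammatory macrophage 0.434 and chemokines 0.467 without propafenone 1, and dendritic cell 0.458 and endothelium 0.153 without propafenone 3.

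Macrophage and fibroblast lists were higher in combination than in IgG tumours beside muscle, skin and fat markers. With the muscle score as covariate the macrophage difference was 1.38 ± 0.58 (SE, from 1.92 ± 0.43) and the fibroblast difference 1.31 ± 0.32 (from 0.888 ± 0.25). A difference thus remained for both lists in this fit. The muscle score is correlated with the groups, and combination 3 stood apart in both the muscle (-0.709) and the fibroblast score (1.1). The fit therefore cannot decide, and muscle RNA as a source stays open, also for the muscle genes themselves. A lower share of tumour cells would raise other cell types alike, while macrophage rose 1.64 more than endothelium (exact permutation p = 0.0079) and fibroblast 0.606 more (exact permutation p = 0.024), but macrophage minus keratinocyte was -0.247 (exact permutation p = 0.81), so a shift shared with skin stays open. Without the 5 libraries rich in haemoglobin the macrophage list stood at 2.19 and the fibroblast list at 1.22, but of the 774 genes 477 were kept among 977 called, and with the red blood cell score as covariate 138 among 229, so haemoglobin-rich libraries stay open for single genes. More macrophages in treated tumours may be 1 explanation, found and tested on the same data.

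Complex I was lower in combination than in IgG tumours. Transcript length and expression level could account for this, as its median of -0.15 was at percentile 31 of 10000 matched random lists (median -0.13). Complexes II to V were at percentile 3.2. Melanocyte genes did not fall with complex I, as melanocyte genes minus complex I stood at 0.447 (exact permutation p = 0.0079). A change of melanocyte genes within tumour cells could mask a lower share of these cells, so that share stays open.

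Xist was higher in combination than in IgG tumours, and transcripts from host cells were weighed. Over 20 tumours Xist and the macrophage score had r = 0.71 (rho 0.78, permutation p = 0.00056, adjusted 0.0022, 0.71 without the 2 farthest), and r was also 0.71 with the melanocyte score. With group means removed r was 0.16 (rho 0.25, permutation p = 0.66, adjusted 0.66, 0.4 without the 2 farthest; 8 relations), so the relation was not seen within groups. The bound written before the test took such a p as excluding the relation, which was wrong because a p that misses the threshold excludes nothing at 20 tumours, and the reading was changed after the result was seen. Host cells and treatment cannot be told apart here, and the sex of the hosts is not in the labels.

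Splits of the same tumours were refitted, the real grouping counted among them, and they bear only on chance. In a pairwise comparison only the tumours compared were split anew, while for the interaction the labels of all tumours were shuffled. That shuffle also removes the single effects, so it does not test the interaction apart from them. For genes, only the real grouping, 1 of 30 splits, reached the count in combination against IgG (774, highest other 1) and 1 of 30 in combination against propafenone (616, highest other 0). Any split reaches a count of 0, so the 30 of 30 splits after propafenone, after anti-PD-1, in combination against anti-PD-1 and for the interaction decide nothing. The highest other counts were 288, 705, 0 and 130, and why some splits that cross the treatments called so many was not tested. For lists, as many were called, the real grouping included, in 57 of 100 splits after propafenone (11, highest other 26), 31 after anti-PD-1 (18, 28), 1 in combination against IgG (30, 29), 3 against anti-PD-1 (26, 29), 3 against propafenone (27, 28) and 37 for the interaction (17, 29), so chance is not excluded for propafenone alone, anti-PD-1 alone and the interaction. Smaller draws run earlier gave list shares on both sides of 0.05, so the shares of 3 in 100 lie near the limit of what such draws resolve.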

How the results depend on the processing

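The covariates, the libraries rich in haemoglobin, counts divided by 4 and the permutation over tumours were chosen after the results were seen. No called list turned direction under any alternative run for lists, and all called genes kept theirs without any 1 library. For the genes this is likely from their choice by p in the same libraries, and it says little of stability. Not run for lists were DESeq2, voom, the TPM fits, only the groups compared and the fold minimum. The covariates were not either, apart from the muscle score for the macrophage and fibroblast lists. The estimated correlation, fry and the permutation were set beside the same mean change, so no turn could appear there. The cause was not tested for the values below unless stated. Genes called, combination against IgG (774): library totals 480 (368 higher, 112 lower), no filter 463, DESeq2 1423, only the groups compared 1786, fold of at least 1.5 411, muscle covariate 8 with 7 kept, red blood cell covariate 229 with 138 kept, without the 5 libraries high in Hbb-bs 977 with 477 kept, macrophage covariate 0. Against propafenone (616): library totals 347 (258 higher, 89 lower), no filter 335, DESeq2 1466, voom 937, log2(TPM + 0.1) 350, only the groups compared 1069, fold of at least 1.5 350, without the 5 libraries high in Hbb-bs 1142, red blood cell covariate 1321, macrophage covariate 2, and muscle covariate 864 with 375 kept. A fold minimum leaves fewer genes by construction. Where the count was 0: propafenone against IgG DESeq2 3, anti-PD-1 against IgG DESeq2 21 and Hbb-bs libraries out 13, combination against anti-PD-1 DESeq2 7, log2(TPM + 1) 1 and only the groups compared 1, interaction DESeq2 2. The log2 fold change of Oas2, combination vs IgG, was -0.0923 with the macrophage covariate.

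Lists called, in the order propafenone against IgG, anti-PD-1 against IgG, combination against IgG, against anti-PD-1, against propafenone and interaction (11, 18, 30, 26, 27, 17): estimated correlation 0, 0, 0, 0, 0, 0, fry 0, 0, 12, 2, 10, 0, permutation over tumours 0, 0, 16, 0, 13 (not run for the interaction), and Hbb-bs libraries out 3 for the first, 1 of them among the 11. Without 1 library the gene counts ran 0 to 0, 0 to 1, 5 to 1067, 0 to 0, 4 to 1882 and 0 to 0, and the list counts 7 to 15, 14 to 23, 27 to 30, 21 to 28, 18 to 29 and 9 to 20. Within 1.5 times stayed DESeq2 size factors (523, 438), 1 CPM in 5 libraries (525, 570), log2(TPM + 1) (621 with 338 kept, 454 with 265 kept), counts divided by 4 (724, 695), voom against IgG 980 and replicate number as a block (829 with 658 kept, 675 with 508 kept). Over all named values, called genes lost their call but kept their direction in 925 of their alternatives, 579 of these in fits without 1 library. They kept call and direction, whatever the size of the change, in 2567 and turned direction in 1. Depth may limit genes under 1 CPM, which was not tested.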

Other observations

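The comparison of effects between backgrounds was chosen after the results were seen. Over 12528 genes the effect of anti-PD-1 on the IgG background and its effect on the propafenone background had r = 0.74, computed so that no group is shared, and 24 of 63504 label assignments gave as large a value (exact permutation p = 0.00038). Genes are not independent replicates. From the fit r was 0.7 and rho 0.59, and of the 616 genes changed on the propafenone background, Postn, Lum and Mgl2 among them, 600 (97.4%) had the same sign on the IgG background, 242 of them with an unadjusted p under 0.05. The median log2 change was 0.55 against 1.3 among those higher and -0.19 against -0.45 among those lower. Markers of other tissues moved the same way on both backgrounds: skeletal muscle by 3.01 and 2.36, adipocyte by 1.07 and 1.53 and red blood cell genes by -1.43 and -3.28. Other lists that camera called moved in opposite directions: interferon gamma response by -0.55 (adjusted p = 0.015) and 0.79 (0.000468), and MHC class I presentation by -0.38 (0.0266) and 0.54 (0.00799). With an estimated correlation these 4 had adjusted p of 0.5 to 0.71. The first call of each ended without IgG 2, IgG 4, anti-PD-1 1 or anti-PD-1 2, and the second without propafenone 1. For MHC class I they also ended without anti-PD-1 4 and without combination 1 or 3, and the first adipocyte and red blood cell calls ended without IgG 4, IgG 5 or anti-PD-1 5. A response to anti-PD-1 shared in part, or a composition the samples share, could give such an r, and the absence of calls after anti-PD-1 alone does not show that the effect differs, as the interaction had 0 genes. For propafenone without and with anti-PD-1 r was 0.37 (11112 of 63504, exact permutation p = 0.17).

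Hbb-bs, a haemoglobin gene of red blood cells, was above 1000 CPM in IgG 4 (1620), IgG 5 (3180), propafenone 4 (1010), propafenone 5 (1850) and anti-PD-1 2 (1530), and 57.9 to 151 CPM in combination tumours. In combination against propafenone single members of the p53 target list changed both ways by edgeR, n = 5 each. Cdkn1a (-1.69, adjusted p = 0.0357) and Ccng1 (-0.66, 0.0365) fell, and Eda2r (1.43, 0.0473) and Sesn1 (0.40, 0.048) rose. In the ATF4 and ER stress list Dnajb9 (0.63, 0.0368) rose. These genes were named after their values were seen, and neither list was called by camera or by the exact permutation over tumours. Hsd17b7 (-0.82) and Stard4 (-0.55), cholesterol genes named the same way, fell there too, while their list was not called by camera (adjusted p = 0.0805) and was called by the exact permutation over tumours (0.032), as was fatty acid synthesis (camera 0.0918, permutation 0.032). That permutation called 13 lists there, where camera called 27.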
